A study of Mus musculus with 26 samples.

How the data were processed

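Total RNA from cultured bone marrow macrophages of male CD1 mice, aged 2 months, was hybridised as biotin-labelled cRNA to Illumina bead arrays, 10 in experiment 1 and 16 in experiment 2. Marrow cells were first expanded in M-CSF at 100 ng/ml. M-CSF and RANKL were each given at 30 ng/ml to the groups with both in experiment 1, per the labels. The sources used here do not give the M-CSF dose of the group with M-CSF alone, nor the doses in experiment 2. The intensity values were deposited by the authors on a linear scale. Within an experiment the arrays have nearly the same distribution, and the experiments have different ones, so the authors' values are taken as quantile normalized within each experiment. GenomeStudio is named in the submitters' processing notes, without a version. The authors also deposited 5 comparison tables with group mean intensity, a detection p-value per group and a DiffScore, a score for differential expression, per the file headers. The ratio in the authors' deposited tables differs from the quotient of the group means by at most 8.2e-07 of its value, and the smallest absolute score in them is 13.0, so they list only part of the probes. These tables pair probes with gene names, which gave names for 7244 of 25697 probes. Only probes the authors listed as differing in a comparison thus carry a name, and counts of list members that passed are raised by this choice. Of 7230 named probes kept in experiment 1, 5086 were called for KO and 5481 under RANKL. Of 7133 in experiment 2, 1158 were called for KO, 1075 for NS398 and 2354 for PGE2. Of 5838 symbols 3969 were current in the RefSeq gene table of GRCm38.p6, 1702 were updated by a synonym and 167 kept as given, among them Lyz, which stands for Lyz1 and Lyz2 and was kept under that name after results had been seen, when it was also made to count once in a list. Unnamed probes were counted and not described. The result of 1 gene is not reported here.

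Values below 32 would have been raised to 32 before taking log2, but the lowest value was 89.4, so this floor changed nothing. Probes above the array's 40th percentile in as many arrays as the smallest group of the experiment has were kept, 17211 in experiment 1 and 18961 in experiment 2. A filter on detection p-values was not used because those are deposited per group and only for listed probes. Each experiment was fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, with 1 mean per group over all its arrays, no covariates, two-sided tests and Benjamini-Hochberg adjustment over its probes. A probe was called at an adjusted p under 0.05. The 5 comparisons stated in the series, the contrasts of KO with PGE2 against WT and of KO against WT with NS398, the overlaps, the gene lists, the filter and the rule for named genes were fixed before the data were examined. The contrast of KO with RANKL against M-CSF alone was added afterwards. The difference of the KO effect between days was not tested, since the experiments were normalized separately.

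Named genes were, per comparison, the 10 called probes with the largest rise and the 10 with the largest fall that have a gene symbol other than a clone name and no overlap between the groups' arrays, 1 probe per gene, and Saa3 in every comparison. In addition the leading 4 members of each list by p-value were named. A probe whose group detection p-value is 0.05 or higher counts as not above background in that group. Where several probes carry one gene symbol each was tested, and lists used the one with the highest mean. Gene lists covered osteoclast genes, acute-phase and secreted defence, cAMP response, cytokines, NF-kappaB, interferon response, cell cycle, cholesterol synthesis, oxidative phosphorylation, glycolysis, prostaglandins, and granulocyte and stromal markers, with other pathway and cell type lists. They were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, with Benjamini-Hochberg adjustment over the lists of a comparison. Lists with fewer than 3 named members, such as B cell markers, were only counted.

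For overlaps of comparisons that share arrays, 100 sets of unchanged groups were simulated as random mixtures of the residuals of the fit. Such groups rarely give calls at the threshold, so a simulated count of 0 shared calls has little weight. The fit was tested on simulated data with known changes on the probes of each comparison. At a log2 change of 0.5 it recovered 80% of changed probes for KO on day 1, 89% for RANKL, 69% for KO on day 3, 68% for NS398 and 67% for PGE2. At a log2 change of 1 it recovered 100%, 100%, 97%, 95% and 95%. False calls made up 3.55% to 5.26% of all calls, and 0 of 20 unchanged lists were called in each. In these simulated data each probe varied independently of the others. The false call rates therefore do not cover probes or list members that vary together, as they can on real arrays. Other splits of the real arrays called as many as 10 lists. A split can keep part of the real group difference and call the same lists. This count therefore cannot show whether camera p-values at the preset correlation are too low for these arrays. As a precaution, calls that hold with an estimated correlation, which the splits did not test, are given more weight. Alternatives included other filters, a background subtraction at the 5th percentile, other variance models, array weights, cyclic loess, the letter r in some array numbers as a covariate, and leaving out each replicate. Figures were drawn with matplotlib 3.10.9.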

Results

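Gene expression was measured with Illumina bead arrays in bone marrow macrophages from male CD1 mice that carried or lacked Cox2, the enzyme (encoded by Ptgs2) that makes the precursor of prostaglandin E2 (PGE2). RANKL is the cytokine that turns these cells into osteoclasts, the cells that resorb bone, and M-CSF keeps them alive and dividing. In experiment 1 the cells were cultured for 1 day, with RANKL and M-CSF in knockout (KO, n = 3) and wild-type (WT, n = 3) cells, and with M-CSF alone in WT cells (n = 4). In experiment 2 they were cultured for 3 days with both cytokines in WT cells (n = 4), WT cells with the Cox2 inhibitor NS398 at 0.1 µM (n = 4), KO cells (n = 4) and KO cells with PGE2 at 1 µM (n = 4). Each array gave 25697 probe intensities. Arrays of one group correlated across probes at 0.993 to 0.996 in experiment 1 and at 0.970 to 0.995 in experiment 2. The number of arrays limits the precision of every value. The series calls the replicates biological without saying that they came from separate mice, so the p-values measure only the spread between these samples. No probe used here carries the name Ptgs2, so the level of the knocked-out gene, which would check the genotype labels, was not analysed here. The experiments were normalized separately, and levels of day 1 and day 3 are set side by side without a test.

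The first comparison asked what RANKL changed in WT macrophages within 1 day. With RANKL secreted defence genes and some matrix-cutting proteases were higher, and genes of dividing cells were lower. The M-CSF dose of the group without RANKL is not given in the sources used here. A difference in M-CSF dose, if there was one, cannot be told from RANKL. Saa3, an acute-phase serum amyloid, went from an intensity of 414 ± 61.7 (SD, n = 4) with M-CSF alone to 67517 ± 1304 (SD, n = 3) with RANKL, a log2 change of 7.36 ± 0.10 (SE; limma adjusted p = 1.9e-21). Chil1, a secreted chitinase-like protein, rose by 7.76 on the log2 scale, Il1b, an inflammatory cytokine, by 6.99, and Ctsk, the collagen-cleaving protease of osteoclasts, by 6.05. Slco2b1, a membrane transporter, fell at least 140-fold, and Ch25h, which makes 25-hydroxycholesterol, fell by 4.65. "At least" marks a fold in which one group was not above background, taken, array by array, against the higher of that probe's value and the lowest value of any probe detected in the group. With RANKL Saa3, Chil1 and the formyl peptide receptor Fpr2 lie near the highest value of the day 1 arrays, 71707, where signals can be saturated, so their day 1 folds are lower bounds. Across the array 2928 probes were higher and 3559 lower of 17211 tested, a balance that cyclic loess turned (3308 and 3093).

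Names exist only for probes the authors listed as differing, and 5481 of 7230 named probes were called in this comparison. Counts of list members are to be read against that share. Of 24 named genes of osteoclast differentiation and function, 14 rose and 4 fell, and 18 rose and 4 fell when adjusted over the list alone. The camera test, which asks whether a list moved more than other genes, gave an adjusted p = 1.3e-04 for it. Beside Ctsk, Mmp14 and Mmp9, proteases that cut matrix, rose by 5.21 and 3.38, and the sodium-proton exchanger Slc9b2 rose at least 18.5-fold. Of 14 acute-phase and secreted defence genes 13 rose and 1 fell, over all probes and when adjusted over the list alone (camera adjusted p = 4.8e-08), among them complement C3 with a log2 change of 5.54 and the protease inhibitor Slpi with 6.41. NF-kappaB feedback and target genes rose in 15 of 17 cases by both counts (adjusted p = 3.3e-06). Sod2, a mitochondrial antioxidant, gained 2.86 and the inhibitor gene Nfkbie gained 2.52. Energy metabolism moved too. Glycolysis and hypoxia genes rose in 17 of 18 cases by both counts (adjusted p = 7.8e-06), with Pfkl, the liver form of phosphofructokinase, at 2.44. Of 29 genes of oxidative phosphorylation 27 rose, or all 29 when adjusted over the list alone (adjusted p = 7.8e-06). All 24 cell cycle and DNA replication genes fell by both counts (adjusted p = 4.8e-08), for example Tk1 with a log2 change of -2.17 and Birc5 with -2.03.

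The remaining 3 lists that camera called in this comparison did not hold with an estimated correlation between their genes. Inflammatory cytokines and chemokines rose in 16 of 24 cases and fell in 7, by both counts (adjusted p = 0.0086, and adjusted p = 0.423 with an estimated correlation), with Ccl5 up by 4.67 and Ccl7 changing by -2.50. Type I interferon stimulated genes rose in 16 of 23 cases, or 17 when adjusted over the list alone, and fell in 4 (adjusted p = 3.8e-04, and adjusted p = 0.370 with an estimated correlation). Genes that respond to cAMP and CREB rose in 10 of 18 cases, or 13 when adjusted over the list alone, and fell in 4 (adjusted p = 0.0068, and adjusted p = 0.135 with an estimated correlation). Arg1, arginase, gained 4.52. The probes of Rpl29, a ribosomal protein, both fell but by different amounts, with log2 changes of -3.52 and -0.98.

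**Figure D1:**
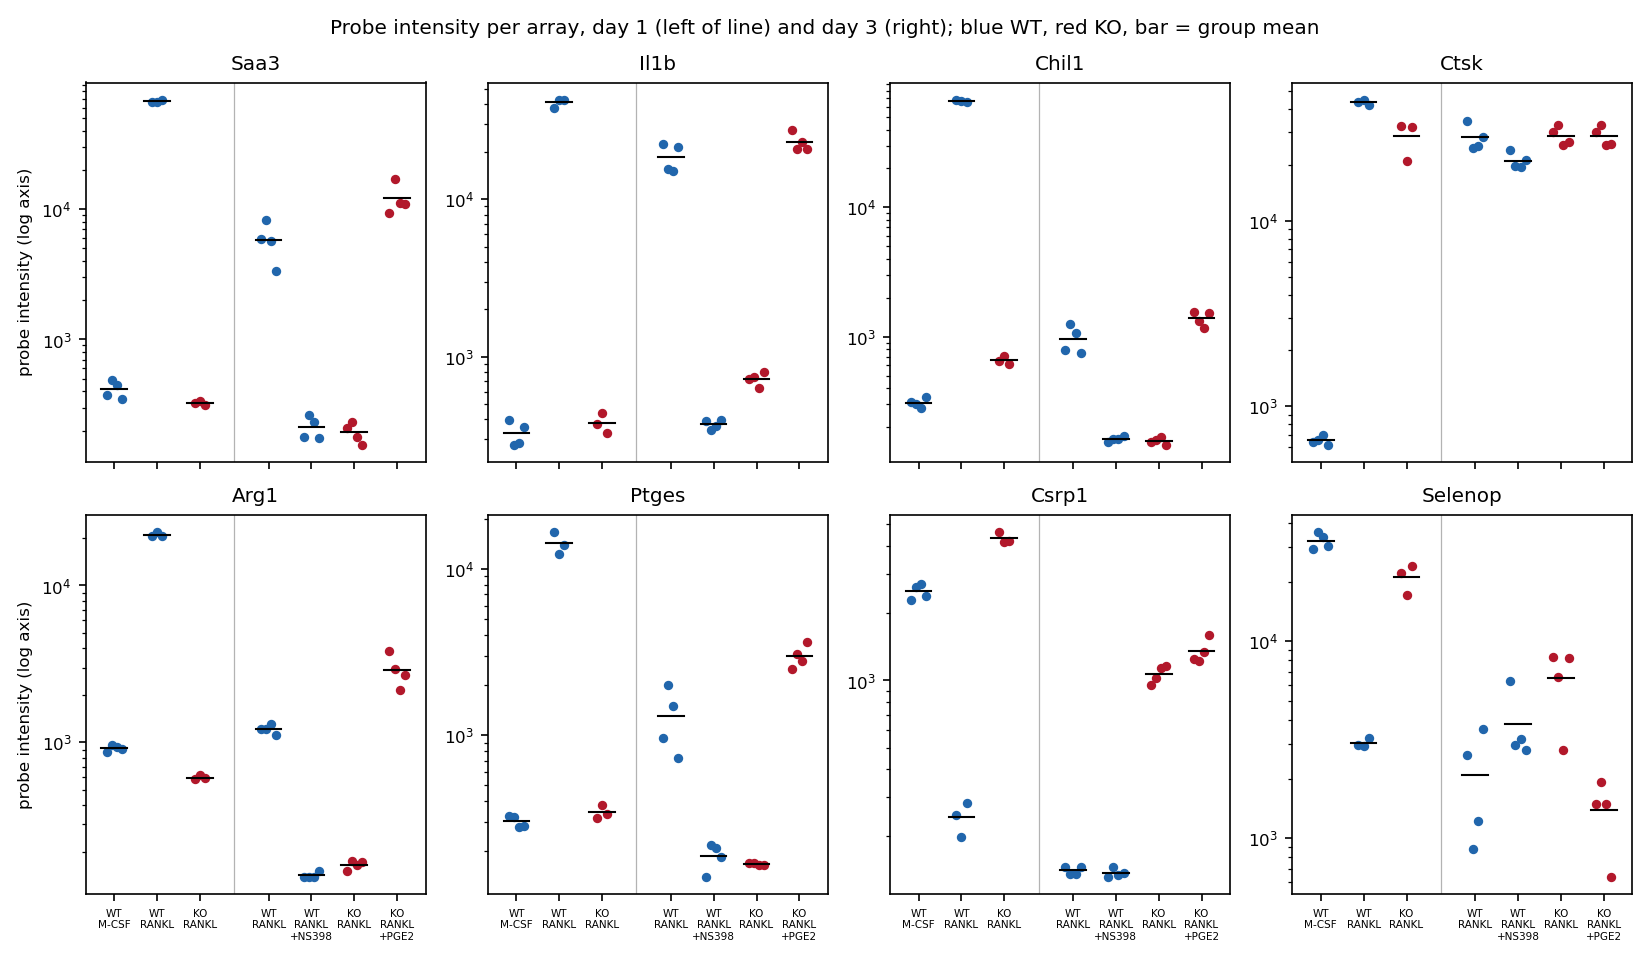
Probe intensity (log axis) of 8 genes on every array, with day 1 to the left and day 3 to the right of each line, WT in blue, KO in red and a bar at the group mean. Saa3, Il1b, Arg1 and Ptges lie lower in the KO arrays and the NS398 arrays than in WT with RANKL, and high again in KO with PGE2.

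The second comparison asked how cells without Cox2 differed from WT cells after 1 day with RANKL. Of the 10 named genes that RANKL had raised most, all but Ctsk, which changed by -0.64, lay far lower in KO cells. Saa3 measured 326 ± 9.05 (SD, n = 3) in KO against 67517 ± 1304 (SD, n = 3) in WT, with a log2 change of -7.70 ± 0.11 (SE; limma adjusted p = 4.8e-21). It was above background in both groups, and its 207-fold fall is a lower bound only because the WT signal can be saturated. Cfb, complement factor B, was at least 109-fold lower, and Il1b and Chil1 changed by -6.77 and -6.66. Clec4e, a receptor for microbial and dying-cell ligands, Fpr2, and Ptges, the synthase that makes PGE2 itself, changed by -5.68, -5.64 and -5.38. Higher in KO were Slco2b1, at least 45.3-fold, the secreted iron binder Ltf, at least 19.2-fold, the LIM-domain gene Csrp1, at least 17.9-fold, the antioxidant enzyme Gpx3 and the cell cycle inhibitor Cdkn1c. In all 3257 probes were higher and 2561 lower in KO, a balance that cyclic loess turned (2656 and 2937).

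Acute-phase and secreted defence genes fell in 13 of 14 cases and rose in 1, by both counts (adjusted p = 1.7e-08). Glycolysis and hypoxia genes fell in 17 of 18 cases, by both counts (adjusted p = 2.5e-06), with Pfkl at -2.25 and Vegfa, a vessel growth factor, at -1.67. NF-kappaB genes fell in 13 of 17 cases, by both counts (adjusted p = 1.6e-04, and adjusted p = 0.067 with an estimated correlation), with Sod2 at -2.34. Inflammatory cytokines and chemokines fell in 15 of 24 cases, or 16 when adjusted over the list alone, and rose in 6 (adjusted p = 0.0010, and adjusted p = 0.309 with an estimated correlation). Ccl5 changed by -4.99 and Cxcl9 by -4.24. Interferon stimulated genes fell in 19 of 23 cases and rose in 2, or in 4 when adjusted over the list alone (adjusted p = 3.0e-06, and adjusted p = 0.235 with an estimated correlation), Gbp2 changing by -3.80 and Isg15 by -2.71. Oxidative phosphorylation genes fell in 18 of 29 cases, or 20 when adjusted over the list alone (adjusted p = 1.6e-04, and adjusted p = 0.067 with an estimated correlation). The osteoclast list went both ways, with 10 of 24 genes lower and 6 higher by both counts (camera adjusted p = 0.168). Car2, a carbonic anhydrase that supplies acid, changed by -2.11, the chloride exchanger Clcn7 by -1.12, and Mitf, a transcription factor of the lineage, by 0.92. Genes of prostaglandin synthesis and reception rose in 6 of 13 cases and fell in 4, by both counts (adjusted p = 0.835), with a median of 0.11 and a mean of -0.29 that differ in sign. Genes that respond to cAMP fell in 8 of 18 cases and rose in 6, or 9 and 6 when adjusted over the list alone (adjusted p = 0.148).

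Markers of other cell types moved with the genotype on day 1. Osteoblast and stromal markers rose in KO in 8 of 9 cases and fell in 1, by both counts (adjusted p = 0.012, and adjusted p = 0.201 with an estimated correlation), with Col6a1 at 1.85 and Col1a1 at 1.35. Neutrophil and granulocyte precursor markers rose in 7 of 11 cases and fell in 4, by both counts, without a call (adjusted p = 0.224). The 2 named B cell markers, of 12 listed, rose, and the 2 named T and NK cell markers, of 14 listed, fell. Hdc, the only named mast cell marker of 12, fell by 2.36, and RANKL had raised it by 2.91 in WT. These few B cell, T and NK cell and mast cell markers, on arrays where 5086 of 7230 named probes passed, do not show that other cells were present. The stromal list was also higher in KO with RANKL than in WT with M-CSF alone, as given below. Whether stromal cells or the macrophages themselves expressed those markers was not tested.

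To ask which genes that RANKL moved in WT cells also differed in KO cells, both day 1 comparisons were laid over each other. Of the probes RANKL raised, 1992 were lower in KO, where independent lists would share 436, and of those it lowered 2437 were higher in KO, where independent lists would share 674. Only 47 and 37 probes moved the same way in both. Across probes the changes correlated at r = -0.873 with a covariance of -0.286. Because both comparisons use the same 3 WT arrays, unchanged groups simulated against those arrays gave r of -0.899 to 0.0905 in 95% of runs, which holds the measured r, covariances of -0.0174 to 4.6e-04, which do not hold the measured one, and no probe called in both. The shared group holds too few arrays to be divided, so the excess was not checked on separate arrays. In a contrast added after seeing the data, KO cells with RANKL were set against WT cells with M-CSF alone. No KO cells with M-CSF alone were measured, so the contrast mixes genotype with RANKL. A baseline KO difference cannot be told from a lost RANKL response. Of the 1992 probes, 401 were still above the WT level with M-CSF alone (the M-CSF level). Of the rest, 1447 did not pass the test and 144 lay below that level. Saa3 was slightly below, with a log2 difference of -0.33 ± 0.10 (SE; limma adjusted p = 0.0285). Osteoclast genes rose in that contrast in 15 of 24 cases and fell in 3, and in 18 and 3 when adjusted over the list alone (adjusted p = 6.6e-09), all 24 cell cycle genes fell (adjusted p = 6.4e-19), and all 9 stromal markers rose (adjusted p = 2.7e-08). These 3 lists hold with an estimated correlation.

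The other lists that camera called in that contrast did not hold with it. NF-kappaB genes were above the M-CSF level in 11 of 17 cases, or 14 above and 1 below when adjusted over the list alone (adjusted p = 4.6e-05, and adjusted p = 0.050008 with an estimated correlation). Granulocyte markers were above it in 7 of 11 cases by both counts (adjusted p = 7.1e-06, and adjusted p = 0.100 with an estimated correlation). Genes that respond to cAMP were above it in 10 of 18 cases and below in 2, by both counts (adjusted p = 0.0106, and adjusted p = 0.152 with an estimated correlation). Acute-phase genes were above it in 7 of 14 cases and below in 3, or 7 and 4 when adjusted over the list alone (adjusted p = 0.0434, and adjusted p = 0.278 with an estimated correlation). Oxidative phosphorylation genes were above it in 6 of 29 cases, or 7 above and 1 below when adjusted over the list alone (adjusted p = 0.0403, and adjusted p = 0.228 with an estimated correlation). MHC class II genes were above it in 6 of 11 cases and below in 2, or 6 and 3 when adjusted over the list alone (adjusted p = 0.0434, and adjusted p = 0.305 with an estimated correlation). Interferon stimulated genes were below it in 6 of 23 cases and above in 1, or 8 and 1 when adjusted over the list alone (adjusted p = 0.0223, and adjusted p = 0.447 with an estimated correlation). Genes of alternative macrophage activation were below it in 9 of 15 cases and above in 3, or 9 and 4 when adjusted over the list alone (adjusted p = 0.0052, and adjusted p = 0.0650 with an estimated correlation).

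**Figure D2:**
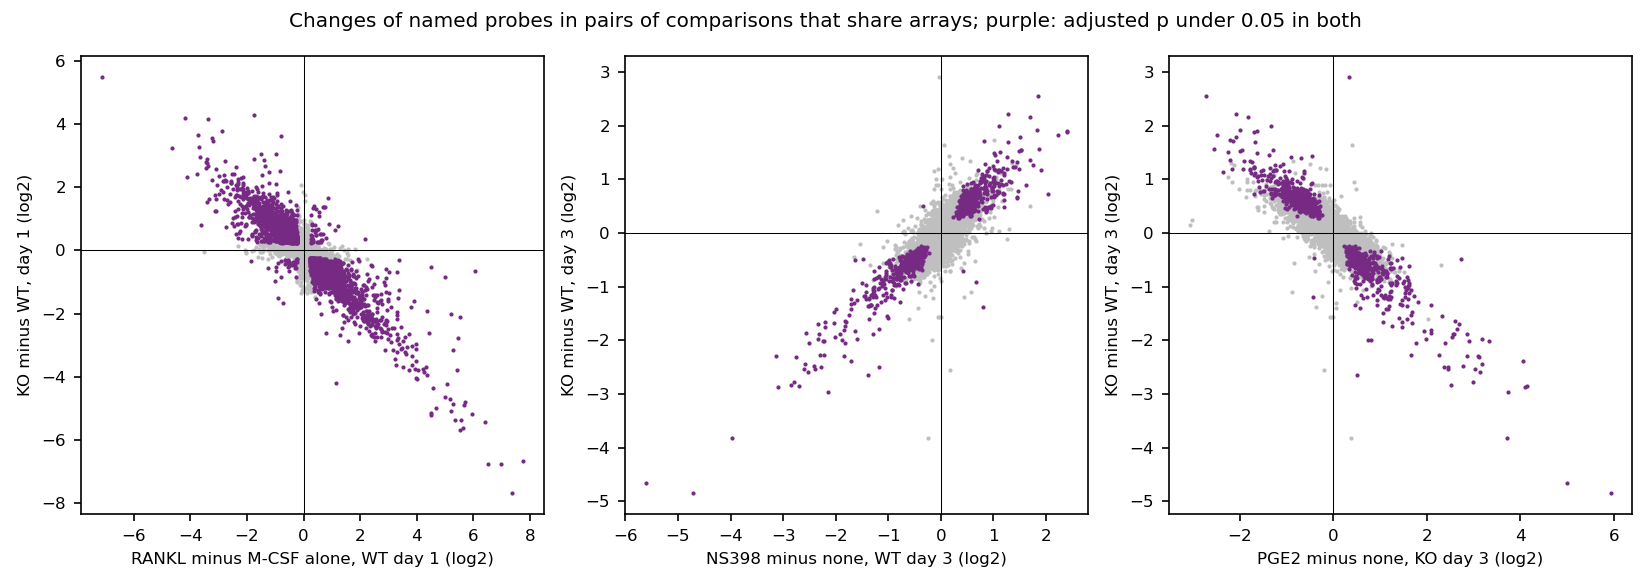
Log2 changes of named probes in pairs of comparisons that share a group, each dot a probe, purple where both comparisons had an adjusted p under 0.05. On day 1 the KO change runs against the RANKL change, with r = -0.873 over all tested probes. On day 3 it runs with the NS398 change, with r = 0.798, and against the PGE2 change, with r = -0.840.

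After 3 days Saa3, Il1b, Fpr2 and Ptges were again among the named genes with the largest falls in KO. Saa3 measured 194 ± 34.8 (SD, n = 4) in KO and 5820 ± 2036 (SD, n = 4) in WT, a log2 change of -4.85 ± 0.24 (SE; limma adjusted p = 2.3e-09). Il1b changed by -4.67, Socs3, a feedback inhibitor of cytokine signalling, by -3.81, Arg1 by -2.87, and Ptges by -2.84. Higher in KO were Csrp1, at least 7.54-fold, the lysozyme probe named Lyz, which stands for Lyz1 and Lyz2 alike, by 2.55, the lipid receptors Lpar6 by 2.15 and Cnr2 by 1.91, and Ccnd1, cyclin D1, by 1.90. Of 18961 probes tested 650 were higher and 558 lower in KO.

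NF-kappaB genes fell in 14 of 17 cases, or 15 when adjusted over the list alone (adjusted p = 2.0e-11), with Tnip1, a brake on this pathway, at -1.32. Inflammatory cytokines and chemokines fell in 13 of 24 cases and rose in 1, or fell in 14 and rose in 1 when adjusted over the list alone (adjusted p = 4.8e-09). The chemokine Cxcl1 changed by -2.29 and Tnf by -1.86. Acute-phase genes fell in 6 of 13 cases, or 10 when adjusted over the list alone (adjusted p = 3.8e-08). Genes that respond to cAMP fell in 6 of 18 cases and rose in 1, or 7 and 3 when adjusted over the list alone (adjusted p = 0.0245, and adjusted p = 0.068 with an estimated correlation), with Il10, an anti-inflammatory cytokine, at -2.02. The osteoclast list stayed without a call (adjusted p = 0.890). Of its 24 genes 1 rose and 2 fell, or 2 and 3 when adjusted over the list alone, and its median of 0.04 and mean of -0.04 differ in sign. Traf6, which relays the RANKL signal, was at least 2.22-fold higher in KO, and Slc4a2, a bicarbonate exchanger, changed by -0.95.

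The stromal and granulocyte lists, mostly higher in KO on day 1, were lower on day 3 where members passed. S100a8, a calcium binder of neutrophils that macrophages also make, changed by -2.39. The granulocyte list fell in 2 of 10 cases, or 5 when adjusted over the list alone (adjusted p = 0.019, and adjusted p = 0.270 with an estimated correlation). The stromal list fell in 2 of 8 cases, or 3 when adjusted over the list alone (adjusted p = 0.027, and adjusted p = 0.306 with an estimated correlation). Of 29 oxidative phosphorylation genes only Cyc1, a part of complex III, passed, at -0.50, and 0 did when adjusted over the list alone (camera adjusted p = 0.0045, and adjusted p = 0.402 with an estimated correlation).

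The inhibitor comparison asked what blocking the enzyme did to WT cells over 3 days. NS398 lowered many of the leading genes that the knockout lowered. Of 3 probes of Sri only 1 was called in KO, and it did not pass with NS398 (-0.25, limma adjusted p = 0.607). Il1b went from 18624 ± 3813 (SD, n = 4) to 374 ± 24.1 (SD, n = 4), a log2 change of -5.62 ± 0.13 (SE; limma adjusted p = 1.9e-13), Saa3 changed by -4.72, Socs3 by -3.98 and Cxcl1 by -3.14. Arg1 was at least 8.49-fold lower, and Cd40, a receptor for T cell help, changed by -2.61. Ccnd1 gained 2.40, Egr2, a macrophage transcription factor, 1.91, Clec7a, the receptor for fungal glucan, 1.87, and H2-Ab1, an MHC class II chain, 1.61. In all 563 probes were higher and 563 lower.

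NF-kappaB genes fell in 16 of 17 cases, or all 17 when adjusted over the list alone (adjusted p = 1.3e-17). Inflammatory cytokines and chemokines fell in 11 of 24 cases, or 16 when adjusted over the list alone, and rose in 2 (adjusted p = 3.6e-08). Acute-phase genes fell in 7 of 13 cases by both counts (adjusted p = 1.5e-06). Genes that respond to cAMP fell in 9 of 18 cases and rose in 2, or 12 and 3 when adjusted over the list alone (adjusted p = 4.8e-06), with Il10 at -2.24 and the growth factor Hbegf at -1.13. Of 23 interferon stimulated genes 7 rose and 1 fell by both counts (adjusted p = 0.017, and adjusted p = 0.109 with an estimated correlation). Genes of cholesterol synthesis rose in 3 of 15 cases, or 6 when adjusted over the list alone (adjusted p = 0.0094, and adjusted p = 0.109 with an estimated correlation), and glycolysis genes fell in 2 of 18, or 3 when adjusted over the list alone (adjusted p = 0.016, and adjusted p = 0.094 with an estimated correlation). Stromal markers, collagens and matrix proteins near background, fell in 3 of 8 cases, or 4 when adjusted over the list alone (adjusted p = 0.0058, and adjusted p = 0.109 with an estimated correlation). The osteoclast list was not called (adjusted p = 0.064), with 1 of 24 genes higher and 2 lower, or 1 and 4 when adjusted over the list alone.

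The rescue comparison asked what PGE2 did to KO cells. It raised 423 of the 558 probes the knockout had lowered and lowered 500 of the 650 it had raised. Both comparisons use the same KO arrays, which by itself makes some overlap. With these arrays divided between the comparisons, 367 to 458 probes were shared over both directions. Saa3 went from 194 ± 34.8 (SD, n = 4) to 12081 ± 3371 (SD, n = 4), a log2 change of 5.94 ± 0.24 (SE; limma adjusted p = 1.4e-10). Il1b gained 4.99, Ptges 4.14, Arg1 4.10, S100a8 4.06, Socs3 3.72 and Gja1, a gap junction channel, 3.19. Lyz changed by -2.71, Clec7a by -2.54, Txnip, a regulator of redox and glucose uptake, by -2.36, and Slc40a1, the iron exporter, by -2.26. In all 1145 probes were higher and 1416 lower.

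Inflammatory cytokines and chemokines rose in 15 of 24 cases and fell in 1, or 17 and 1 when adjusted over the list alone (adjusted p = 1.55e-08). Acute-phase genes rose in 7 of 13 cases, or 10 when adjusted over the list alone (adjusted p = 9.7e-07), with the iron-trapping protein Lcn2 at least 7.10-fold higher. NF-kappaB genes rose in 12 of 17 cases, or 13 when adjusted over the list alone (adjusted p = 2.3e-06), and cAMP genes rose in 7 of 18 and fell in 2, or 9 and 2 when adjusted over the list alone (adjusted p = 0.012). Il10 gained 2.90, and Dusp1, a phosphatase, changed by -1.04. Granulocyte markers rose in 5 of 10 cases, or 6 when adjusted over the list alone (adjusted p = 0.00355, and adjusted p = 0.127 with an estimated correlation), and stromal markers in 5 of 8, or 6 when adjusted over the list alone (adjusted p = 4.7e-04, and adjusted p = 0.068 with an estimated correlation). Oxidative phosphorylation genes rose in 6 of 29 cases, or 10 when adjusted over the list alone (adjusted p = 0.0019, and adjusted p = 0.398 with an estimated correlation). The osteoclast list was not called (adjusted p = 0.815), with 4 of 24 genes higher and 3 lower by both counts.

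The day 3 arrays spread within their groups along a shared axis that holds 35.1% of the variance left after group means. The KO arrays with PGE2 lie at 0.16 to 1.79 on it, in SD units, and the other KO arrays at -1.35 to -0.03. PGE2 replicate 21r and KO replicate 12r lie side by side near the middle. WT replicates 2 and 4 lie at 1.18 and 1.33. The positions keep the differences between groups, so as a covariate the axis also takes away any PGE2 effect that lies along it. With this axis as a covariate, chosen after seeing the data, PGE2 raised 474 probes and lowered 506. Actb (adjusted p = 0.193), Selenop (adjusted p = 0.062) and Hspa8 (adjusted p = 0.056) lost their calls. Such losses cannot tell spread within groups from a PGE2 effect along the axis. Of 3 probes of Actb, a cytoskeletal actin, 2 passed the test in the first fit, with changes from -3.07 to -0.89.

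**Figure D3:**
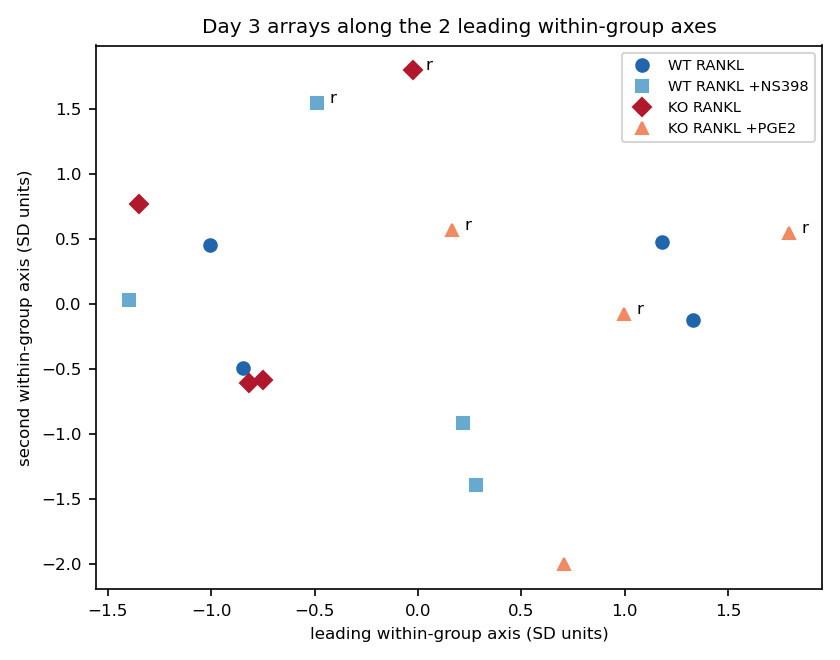
Positions of the day 3 arrays on the leading and the second within-group axis, in SD units, coloured by group, with the arrays numbered with r marked. The positions keep the differences between groups.

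**Figure D4:**
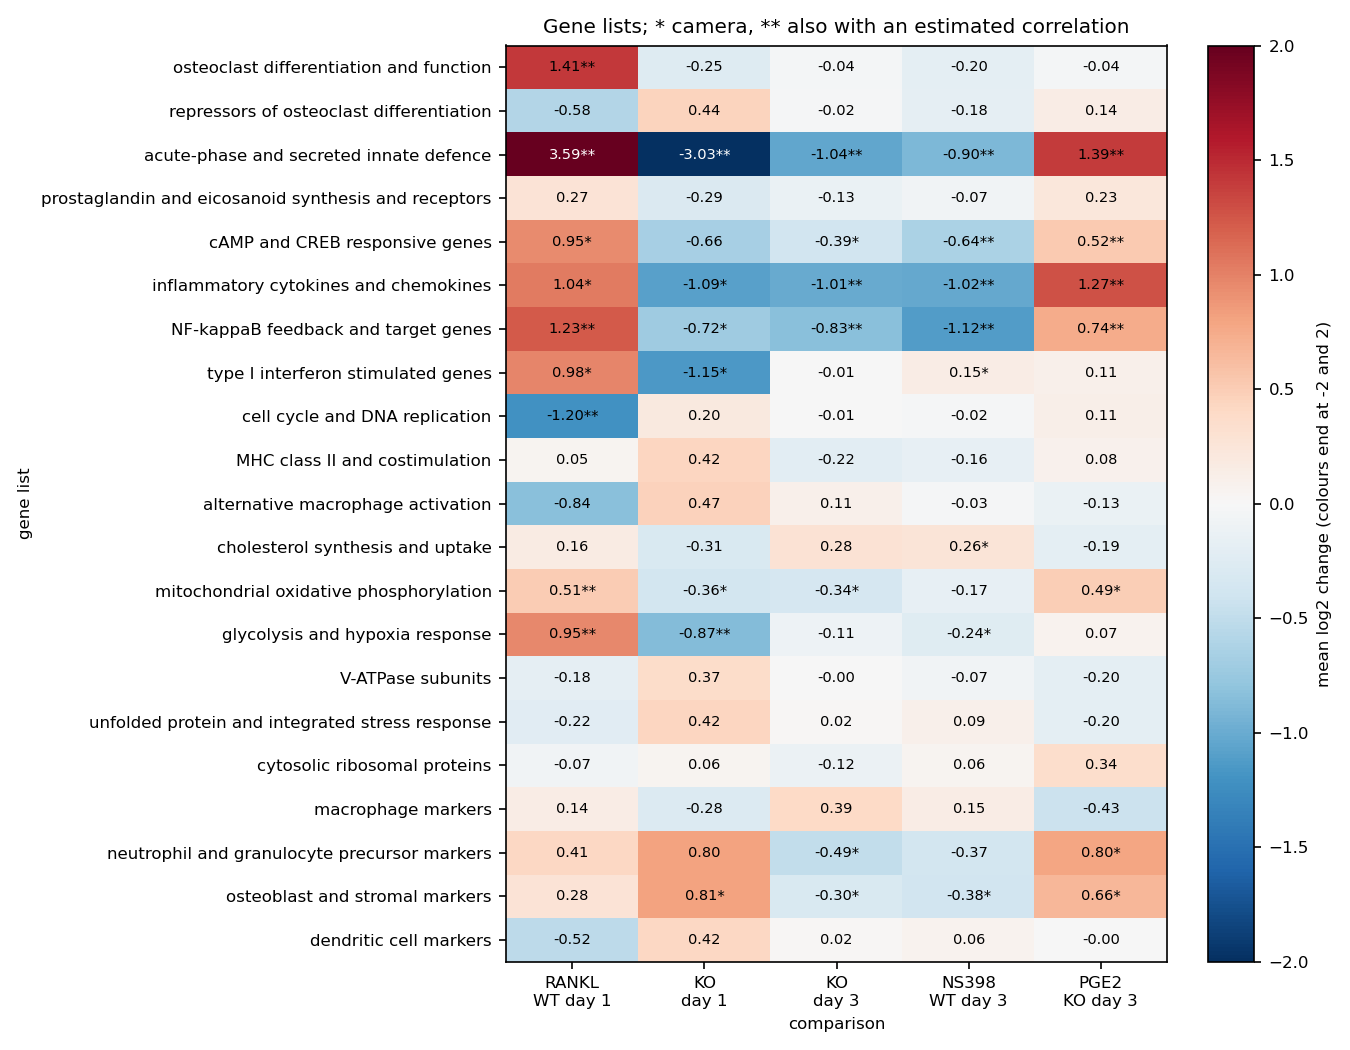
Mean log2 change of the named members of each gene list in the 5 comparisons. A star marks a camera call and a double star a call that also holds with an estimated correlation. Inflammatory, acute-phase and NF-kappaB lists have a double star in all 3 day 3 comparisons.

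Comparisons on day 3 overlapped. Probes higher in KO and with NS398 numbered 351, where independent lists would share 19.3, and probes lower in both 369, where they would share 16.6. Across probes r was 0.798 with a covariance of 0.0612. Simulated unchanged groups against the same WT arrays gave r of -0.354 to 0.902, which holds the measured r, covariances of -0.0042 to 0.0349, which do not hold the measured one, and as many as 329 shared calls in one simulation. With the WT arrays divided 2 and 2 between the comparisons r was 0.288 to 0.729, with 321 to 375 shared calls. Probes lower in KO and higher with PGE2 numbered 423, against 33.7 for independent lists, and the reverse 500, against 48.5, with r = -0.840 and a covariance of -0.0863. The simulations gave r of -0.881 to 0.283, which holds the measured r, and covariances of -0.0326 to 0.0037, which do not hold the measured one. The KO arrays divided likewise gave r of -0.803 to -0.639 and 367 to 458 shared calls. The NS398 and PGE2 comparisons share no arrays, and 369 probes were lower with NS398 and higher with PGE2, against 34.0 for independent lists, and 412 the reverse, against 42.0. Their r of -0.720 lies within the simulated -0.724 to 0.760, while their covariance of -0.0710 lies outside the simulated -0.0184 to 0.0153. The simulations called 0 probes in both, which has little weight because unchanged groups rarely give calls.

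Of the 1992 probes that RANKL raised and the knockout lowered on day 1, 1932 were tested on day 3. There 284 were lower in KO, 287 lower with NS398 and 441 higher with PGE2, and 200 were all of these, covering 165 named genes, where independent lists would share 9.63. The NS398 and PGE2 comparisons, which share no arrays, had 226 of these probes in common, where independent lists would share 65.5. Simulated unchanged groups, run after seeing the counts, shared 0 in both cases. Such groups rarely give calls, so this has little weight. KO cells given PGE2 still differed from WT cells at 227 probes, 122 higher and 105 lower. Saa3 stood 2.13-fold above WT in them (log2 1.09 ± 0.24 (SE), limma adjusted p = 0.039), a call lost on leaving out any of 6 of the arrays, with adjusted p = 0.075 to 0.125. KO cells differed from WT cells with NS398 at 140 probes, 70 higher and 70 lower.

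A set of 38 probes covering 35 genes differed in KO from WT, from WT with NS398, and, with PGE2 present, still from WT, always in the same direction, 14 higher and 24 lower. Csrp1, Traf6 and the MHC genes H2-Ea, H2-Eb1 and H2-Q7 were among the higher ones, and Lad1, a basement membrane anchor, Abhd1 and 1 of the probes of the calcium binder Sri were lower. The Sri probe changed by -3.83 on day 3. It was the only 1 of 3 Sri probes called there, and their changes ran from -3.83 to -0.04, so a fall of the gene is not shown. The shared direction holds for day 3 only. In KO on day 1 Csrp1 (4.17), H2-Ea (3.07), H2-Eb1 (2.52) and Lad1 (-1.48) changed the same way. H2-Q7 (-1.10) and the Sri probe (1.73) changed the other way there. Traf6 did not pass on day 1, and only 1 probe of Abhd1 did (-0.27).

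Of 1196 probes called in KO on day 3 and tested on day 1, 844 were called on day 1, 679 in the same direction and 165 in the opposite one. The authors' deposited table gives a ratio of 207 between the WT and KO means of Saa3 on day 1. The direction of every kept probe in the authors' deposited tables was the one found here (4988, 5301, 1147, 924 and 2458 probes for KO on day 1, RANKL, KO on day 3, NS398 and PGE2). Those ratios are quotients of the same group means, so this was largely fixed in advance. Of these probes 4639, 5168, 965, 835 and 2078 were also called here. Lists called by camera held with an estimated correlation for the acute-phase list in all 5 comparisons, and for NF-kappaB genes under RANKL, NS398, PGE2 and in KO on day 3. They held also for inflammatory cytokines in the 3 day 3 comparisons, for cAMP genes under NS398 and PGE2, for glycolysis genes in both day 1 comparisons, and for osteoclast, oxidative phosphorylation and cell cycle genes under RANKL.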

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

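The tests of the second axis, of genes near Ptgs2 in the set below and of granulocyte markers were chosen after their results had been seen, as was the reading of the test on both days and the use of an interval in the test of single probes. Of 330 groups of 4 arrays looked at, 25 held an array set apart from the other 3, where chance gives about 1 in 20. The gap to the nearest array as a share of the group's range stands after each. In WT with M-CSF alone replicate 6 was high for Vsig4 (0.906) and low for Rgs1 (0.837), replicate 2 was low for Fcrls (0.891) and replicate 5 high for Traf1 (0.834). In KO on day 3 replicate 8 was low for Lpar6 (0.858), for Src (0.831) and for the oxidative phosphorylation score (0.915), and high for Cd9 (0.850). In the same group replicate 12r was low for Arhgap25 (0.864), Slco2b1 (0.987), Timp1 (0.950), Ltf (0.888) and Retnlg (0.892), and high for Tnip1 (0.850). With NS398 replicate 16r was high for Arg1 (0.954), the cAMP score (0.841) and the cholesterol score (0.934), replicate 13 high for Serpinb2 (0.852) and Hk2 (0.926), and replicate 17 low for Cd40 (0.905). In KO with PGE2 replicate 21r was low for S100a8 (0.879) and 24r low for Txnip (0.873). In WT on day 3 replicate 3 was low for the acute-phase score (0.873) and high for Nfkb2 (0.937), and replicate 6 high for Sqle (0.850).

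In 6 of 79 genes looked at, every KO array lay on one side of WT on day 1 and on the other on day 3, a difference between days that was not tested. The day 3 log2 differences were -2.56 for Cd300ld, -3.83 for 1 of 3 probes of Sri, 0.41 for Vegfa, -0.65 for Sparc, -2.02 for Il10 and -1.86 for Tnf.

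Day 3 arrays spread within groups along a leading axis (35.1% of the residual variance) and a second one (25.2%). With the leading axis as a covariate only 33.1% of the PGE2 calls remained with their direction, as their median absolute log2 change went from 0.58 to 0.36 while the median standard error went from 0.126 to 0.129, so much of the PGE2 effect lies along an axis that also separates arrays of one group. The positions used as the covariate keep the differences between groups, so part of this loss was fixed by the way they were computed. The mean change of oxidative phosphorylation genes under PGE2 went from 0.49 to 0.10 in the same way. For the same reason, this cannot tell a list that follows the axis from a PGE2 response along it. The letter r in array numbers, whose meaning is not given in the sources used here, explained 2.99% of the positions on the leading axis within groups, which argues against it as the source of that axis, and 76.7% on the second one, the largest share of 64 placements (exact p = 0.0156). A batch marked by r may therefore shape the second axis, and 3 of the 4 arrays with PGE2 carry it. With r as a covariate PGE2 gave 1175 probes higher and 1582 lower, and 79.9% of its calls were kept.

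The 35 genes whose KO difference on day 3 NS398 did not match and PGE2 did not remove included 4 of the 41 tested genes within 200 genes of Ptgs2 on its chromosome in the order of GRCm38.p6, Csrp1, Lad1, Rgl1 and Trmt1l (Fisher's exact p = 1.0e-04, two-sided). Genes there were also called in one direction on both days more often, 9 of 41 against 577 of 5697 overall (Fisher's exact p = 0.0315, two-sided, a test planned before the data were examined, with the window, the shared direction and its reading chosen later), though Chil1 (-2.54), Rgs1 (2.04), Soat1 (0.76) and Lad1 among the 9 also changed that way with NS398. Alleles carried along with the knocked-out gene are a candidate explanation for the 4 genes of the set. However, Lad1 also fell with NS398 (-1.39) and rose with PGE2 (0.52). Rgl1 was lower in KO on day 3 (-1.39) and higher on day 1 (0.35). The other genes of the set were not placed within 200 genes of Ptgs2. Whether they are linked to it over a longer distance, or to each other, was not tested. Variants under single probes could not be judged, since only 6 genes of the set have more than 1 tested probe and 4 of them a probe without a call, against 194 of 286 other genes (Fisher's exact p = 1, two-sided). Loss of Cox2 from early in life, which an inhibitor given for 3 days would not match, stays open and was not tested.

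Granulocyte markers such as Ltf were higher in KO than in WT with RANKL on day 1. Carried-over granulocytes would raise all of their abundant transcripts, yet 4 of 11 markers were lower in KO, S100a8 and S100a9 among them. Against M-CSF alone 7 rose and 0 fell (limma), and RANKL itself moves S100a8, so granulocytes and expression by the macrophages cannot be told apart. No other biological explanation of these markers was tested.

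Among splits of the arrays, the real one gave the most called probes under RANKL (6487, at most 0 in another split, 1 of 35 splits as large), KO on day 3 (1208, at most 0), NS398 (1126, at most 996) and PGE2 (2561, at most 0). The same held for KO with PGE2 against WT (227, at most 42), KO against WT with NS398 (140, at most 1) and KO against M-CSF alone (2704, at most 375). A share of 1 in 35 is the smallest these splits can give, and no adjustment was made for the number of counts. Chance is thus made less likely but not excluded. The split with 996 points to structure among the WT and NS398 arrays. For KO on day 1 the 10 splits are too few for a share under 0.05, with 5818 calls and at most 0 in another split. For the number of called gene lists, the real split was the largest for KO on day 3 (7 lists, at most 6 in another split). It was not for RANKL (9, at most 10, 8 of 35 splits as large), NS398 (8, at most 10, 9 of 35) and PGE2 (7, at most 8, 4 of 35). Chance is therefore not excluded in those comparisons. A split can keep part of the real group difference and call the same lists, so these counts cannot decide. For KO on day 1, with 7 lists and at most 9, 5 of 10 splits were as large, so chance is not excluded there either.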

How the results depend on the processing

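Cyclic loess, the leading axes as covariates, the arrays numbered with r left out and the contrast against M-CSF alone were chosen after seeing the data. Of the recomputed values of named genes and lists, 1927 kept direction and side of the threshold, 34 lost it, 2 passed it newly, and 1 turned direction, the osteoclast list for KO on day 3 under fry (adjusted p = 0.935). Where a count moved by over 1.5 times, array weights called 1273 higher and 1068 lower for KO on day 3. The leading axis gave 474 and 506 for PGE2, and both axes gave 991 and 939 for KO on day 3, 1218 and 1135 for NS398, and 711 and 803 for PGE2. Without arrays numbered with r PGE2 gave 251 and 338, with 1 array with PGE2 left and assumed to vary like the other groups. In that setting Actb, Atp6ap2, Selenop, Hspa8 and Stap1 lost their calls. For the other settings the cause was not tested. Camera with an estimated correlation called 2 lists for KO on day 1, 3 for KO on day 3, 4 for NS398 and 4 for PGE2, and fry called 21, 11, and 12 for KO on day 1, KO on day 3 and PGE2, and 20 for RANKL. Leaving out one array gave 373 to 619 higher probes for NS398 (373 without WT replicate 2). For PGE2 it gave 722 to 1263 higher (763 without PGE2 replicate 24r, 722 without KO replicate 8) and 934 to 1479 lower (934 without KO replicate 8). It gave 66 to 130 lower for KO with PGE2 against WT (67 without PGE2 replicate 20, 68 without 23r, 66 without WT replicate 6, 69 without WT replicate 2) and 36 to 81 higher for KO against WT with NS398 (37 without NS398 replicate 17, 36 without 18, 44 without KO replicate 8). Elsewhere the ranges of higher and lower probes were 2773 to 2947 and 2268 to 2361 for KO on day 1, 2604 to 2805 and 3120 to 3425 for RANKL, 437 to 737 and 385 to 624 for KO on day 3, and 930 to 1220 and 1120 to 1393 for KO against M-CSF alone. They were 417 to 600 lower for NS398, 86 to 140 higher for KO with PGE2 against WT, and 51 to 79 lower for KO against WT with NS398. Floors of 16 and 64 change nothing, as the lowest value is 89.4, and quantile normalization was not run because the values already are quantile normalized. No paired analysis was possible because the compared groups share no replicate numbers.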

Other observations

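Some lists had members past the test without a camera call, on arrays where 5086 of 7230 named probes passed for KO on day 1. Camera did not find that they moved more than other genes. Unfolded protein and stress response genes rose in KO on day 1 in 10 of 13 cases and fell in 3, by both counts (adjusted p = 0.150), and V-ATPase subunits, the proton pump that acidifies lysosomes and the resorption pit, rose in 7 of 11 and fell in 1, by both counts (adjusted p = 0.224). Cell cycle genes were higher in KO on day 1 in 10 of 24 cases, or 11 when adjusted over the list alone (adjusted p = 0.232). With PGE2 on day 3, 6 of these 24 rose and 2 fell, or 8 and 3 when adjusted over the list alone (adjusted p = 0.190). Genes of alternative macrophage activation fell with RANKL in 9 of 15 cases and rose in 6, by both counts (adjusted p = 0.254).

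In KO cells given PGE2 against WT cells on day 3, acute-phase genes were higher in 5 of 13 cases, or 6 higher and 1 lower when adjusted over the list alone (adjusted p = 0.0011). Stromal markers were higher in 2 of 8 cases, or 5 when adjusted over the list alone (adjusted p = 4.4e-04, and adjusted p = 0.072 with an estimated correlation), and inflammatory cytokines in 0 of 24, or 4 when adjusted over the list alone (adjusted p = 0.012). In KO against WT with NS398, NF-kappaB genes were called higher as a list (adjusted p = 3.6e-04) with 1 of 17 members past the test, or 6 when adjusted over the list alone. There cAMP genes were higher in 2 of 18 cases, or 2 higher and 1 lower when adjusted over the list alone (adjusted p = 0.0083), and interferon stimulated genes were lower in 4 of 23, or 5 when adjusted over the list alone (adjusted p = 0.0049, and adjusted p = 0.0615 with an estimated correlation).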
